A study of Mus musculus with 11 samples.

How the data were processed

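Satellite cells from mouse muscle at 0 and 4 days post injury were profiled by droplet-based single-cell RNA sequencing in 11 libraries. Per the submitters' processing notes, base calls were made with CASAVA 1.8 and bcl2fastq 2.17 and reads were aligned to GRCm38 with GSNAP (version 2013-10-10). The counting program, UMI handling, cell filters and clustering method are not given in the sources used here. The values deposited by the authors were counts of UMIs per gene and cell, with a class name for each cell, for 23007 cells and 52596 features. Of these features 1 was the tdTomato reporter, whose counts were included in library sizes and in the rows given to edgeR. Sequencing reads were not analysed here.

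Depth per library ran from 2068295 to 3202292 UMIs at 0 dpi and from 8877514 to 48238633 at 4 dpi. At 0 dpi the share of cells with at least 500 detected genes was 59.1%, 90.8% and 99.2% (no antibody, aRW, aN2). All deposited cells were used. Scrublet, with an expected doublet rate of 0.05, called 60 of 23007 cells (0.261%), too few for a working call, so doublets were kept and the planned repeat without them was not run.

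Counts were summed per library over all cells, or over the cells of a class. edgeR 4.0.16 (filterByExpr, TMM scaling, robust quasi-likelihood F tests) in R 4.3.3 called genes at an adjusted p (Benjamini-Hochberg) under 0.05. The injury comparison used 7 libraries in the 3 conditions held at both times, with condition as a covariate. The antibody comparisons used the 7 antibody libraries at 4 dpi, with antibody and ActD as factors, and the antibody by time comparison the 5 libraries with ActD of aRW and aN2. Differentiation and Primary sums were compared within 4 libraries, for Notch genes only. That fit also held the Proliferation sums, which entered its filter, scaling and spread (12 sums, 6 residual degrees of freedom). The injury and antibody models each left 3 residual degrees of freedom. Group levels are TMM-normalised CPM (counts scaled to a common library total) as mean and SD, and fold changes are edgeR estimates with SE. For genes with 0 counts in a group a floor of 3 counts gave the smallest fold. The aN2 and aRW libraries at 0 dpi, 1 each, were compared as ratios of untransformed CPM with 95% Poisson or binomial intervals, and intervals cover counting error only. Whether libraries of a group came from separate animals is not stated in the labels, so p-values measure the spread between libraries. In the injury and antibody models several groups held 1 library, so part of that spread is departure from additive effects.

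Lists were written before the data were examined. They covered Notch pathway genes, Notch target genes, Notch-linked collagens, satellite cell quiescence, S phase, G2 and M phase, dissociation and immediate early genes, heat shock, p53 targets, interferon response, class I antigen presentation, extracellular matrix, glycolysis, oxidative phosphorylation, cytosolic ribosomal proteins, mitochondrially encoded genes, and myogenic commitment and differentiation, with markers of 13 kinds of cells. Lists were tested with limma 3.58.1 (camera on voom values, preset correlation 0.01) and again with a correlation estimated from the data. The second test was run without voom weights because the weighted estimate for injury varied with the numerical library; this was decided after both had been seen, and neither called any list. List members were also adjusted over the list alone. At 0 dpi list medians were placed among 10000 random lists matched on expression in 20 bins, and the range that labels a median was changed to 1000 Poisson draws after a first output had been seen.

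Genes named per comparison were Notch2, Dll1 and the Notch target genes, the 8 largest increases and 8 largest decreases among called genes with an average log2 CPM of at least 4 and the same direction in every matched pair, leaving out numbered gene models, and up to 4 members of each list with the smallest adjusted p. At 0 dpi the 5 largest ratios each way were named among genes with at least 50 CPM. Genes of the direct comparison of antibodies were all named.

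Class shares carry exact binomial intervals and were compared by exact permutation within ActD strata. Classes were to be made anew without Notch genes; the authors' annotation was used instead because it came with the counts, so clustering resolution and share denominators were not varied. Class shares were compared only where no library's 10 leading genes held more markers of another class, which ECM, Proliferation and Quiescence did not meet. Notch2-high met it, with no marker of any class among its leading genes, but was set aside because it is named by a gene under study and no markers had been fixed for it. This left Primary and Differentiation, although Primary had no marker of its own in some libraries. Single-class fits were also run in Proliferation, Notch2-high and Quiescence cells, and their values draw no comparison of classes. Fold changes under both antibodies were compared with 50 simulated sets of unchanged groups sharing the same controls. Each design was tested on simulated data with 200 changed genes, and the share of false calls was 10.8% for injury, 10.8% for aN2, 6.57% for aDll1, 10.4% for ActD, 15.4% for aN2 minus aDll1 and 46.3% for antibody by time, above the 5% aimed for. Libraries of a group were checked for identity; chi-squared per degree of freedom between them was 59.5 for aRW and 25.2 for aDll1, so they were not duplicates.

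Alternatives chosen before the data were examined were DESeq2 1.42.0, RLE scaling, no expression filter, cells with at least 1000 genes, single classes, subsets of libraries and leaving out each library. Those chosen after seeing the data were at least 500 genes, Notch2-high cells only, all cells but ECM, counts thinned to equal totals and libraries of a single run of cell numbers. Further computing used Python 3.11.15, scanpy 1.11.5, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and scikit-learn 1.9.0.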

Results

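The series comprised 11 single-cell libraries of satellite cells, the stem cells of mouse skeletal muscle, profiled with a droplet kit that counts transcript molecules by unique molecular identifiers (UMIs). Libraries came from 0 and 4 days post injury (dpi), with antibodies named aRW (the control), aN2 (blocking the receptor Notch2) and aDll1 (blocking the ligand Dll1), and with or without a treatment named ActD in the labels. At 0 dpi there was 1 library each without antibody or ActD (2068295 UMIs from 2062 cells), with aRW and ActD (2634360 from 1679) and with aN2 and ActD (3202292 from 1447). At 4 dpi the library without antibody or ActD held 20235555 UMIs from 2091 cells. The 3 aRW libraries at 4 dpi held 13687913 (ActD, library 1), 20712571 (ActD, library 2) and 16716842 UMIs (no ActD), from 1752, 2609 and 1494 cells. The aN2 libraries held 28121541 UMIs from 3663 cells with ActD and 48238633 from 3197 cells without it, and the aDll1 libraries, both with ActD, held 8877514 and 14619893 UMIs from 1214 and 1799 cells. Cells were shallower at 0 dpi, with median UMI counts per library of 865, 1344 and 1895, than at 4 dpi, where medians ran from 6536 to 13107. The labels did not say whether libraries of a group came from separate animals, so p-values measured only the spread between these libraries, which may be technical. Where groups held 1 library, part of that spread was departure from additive effects of the factors.

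The authors' annotation divided the 0 dpi cells into the classes Quiescence and Notch2-high and the 4 dpi cells into Primary, ECM, Proliferation, Differentiation and Notch2-high. Under aRW, 39.6% ± 6.98 of cells (SD, n = 3) were Primary and 11.7% ± 1.89 were Differentiation. Under aN2 the shares were 15.7% ± 3.04 and 27.2% ± 1.07 (n = 2), which stratified by ActD was a difference of -25.7 and 16.1 percentage points. The exact two-sided permutation p was 0.167 for each class, the smallest that this design allows. With ActD, Primary cells made up 35.8% ± 3.46 under aRW and 5.73% ± 2.84 under aDll1 (n = 2 each), and Differentiation cells 12.8% ± 0.367 and 39.6% ± 7.73. The differences of -30.1 and 26.8 points had an exact permutation p of 0.333, again the smallest possible. Neither design could pass 0.05. Proliferation cells ran from 15.4% to 28.4% in the aRW libraries, stood at 39.5% and 42.0% under aN2 and at 39.9% and 51.3% under aDll1. ECM cells ran from 8.78% to 16.4% under aRW, were 4.86% and 5.47% under aN2, 1.81% in aDll1 library 1, and 0 of 1799 cells in aDll1 library 2, which allows up to 0.167% at 3 counts of the total (exact binomial limit 0.205%). The 10 leading genes of the ECM class included 3 tenocyte markers in aDll1 library 1 and 3 fibroblast markers in aN2 without ActD, and those of the Proliferation class included the macrophage gene Lyz2 and no cycling marker in aRW library 2 with ActD. Both shares therefore stand as values only. Notch2-high cells, a class named by a gene under study, also stand as values only. They ran from 11.6% to 16.9% under aRW, and were 15.6% and 6.66% under aN2 and 5.52% and 10.8% under aDll1. The genes behind the annotation are not given in the sources used here, so shares and expression are not independent.

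**Figure D1:**
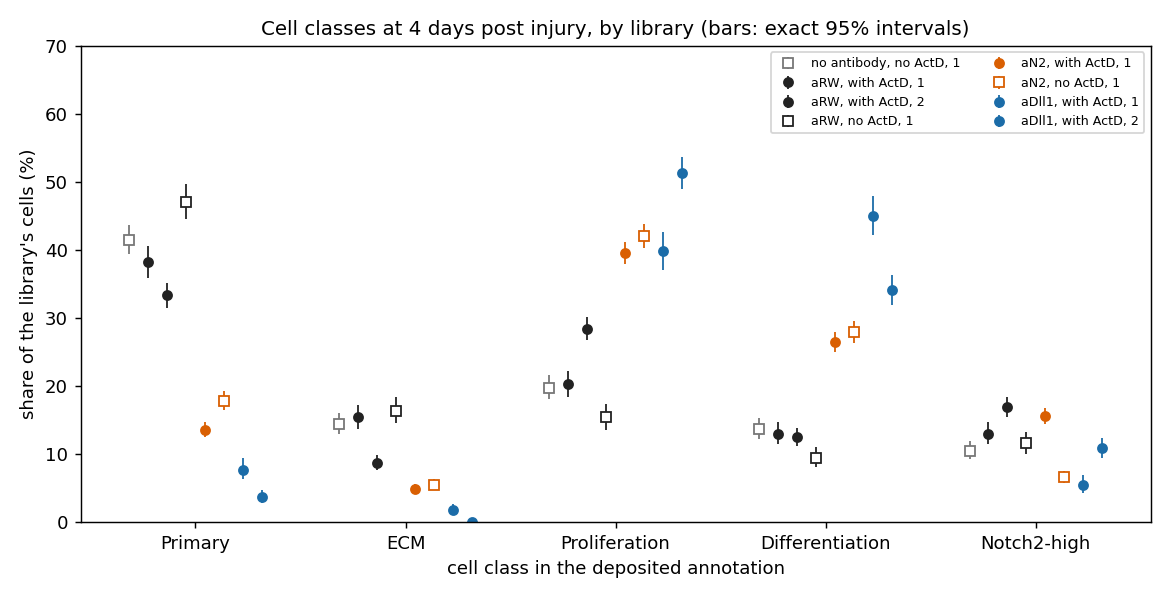
Share of each 4 dpi library's cells (y axis, percent) in each annotated class (x axis), colored by antibody, with exact 95% binomial intervals. Differentiation cells made up 9.50% to 13.0% of the aRW libraries, 26.5% and 28.0% of the aN2 libraries and 45.1% and 34.1% of the aDll1 libraries.

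Comparing 0 with 4 dpi addressed how satellite cells of resting muscle differ from those of regenerating muscle, over 3 libraries at 0 dpi and the 4 libraries at 4 dpi of the same conditions. Of the 3 conditions 1 was aN2 with ActD, so any aN2 effect at 4 dpi enters these fold changes. Genes of quiescent satellite cells fell. Chrdl2, a chordin-like secreted factor, went from 223 ± 54.4 CPM (counts scaled to a common library total with TMM factors; mean ± SD, n = 3) to 0.573 ± 0.132 (n = 4), a log2 fold change of -8.66 ± 0.35 (SE; edgeR adjusted p = 4.14e-05). Calcr, the calcitonin receptor, fell from 40.8 ± 2.66 to 0.688 ± 0.546 CPM, and the surface antigen Cd34 from 106 ± 47.0 to 6.43 ± 1.44 CPM. Myog, a transcription factor of differentiating myoblasts, rose from 16.2 ± 17.5 to 1247 ± 821 CPM (log2 fold change 6.56 ± 0.49, adjusted p = 0.000146). The receptor Notch2 fell from 246 ± 95.4 to 67.4 ± 13.3 CPM (-1.97 ± 0.34, adjusted p = 0.00238). The share of Notch2-high cells was also lower at 4 dpi (14.0% against 25.3%), which enters this sum over all cells. Within Notch2-high cells, a fit chosen after seeing the data, Notch2 had -1.59 (edgeR adjusted p = 0.00457).

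Of 29 measured genes of the satellite cell quiescence list, 23 fell and 2 rose (the same 23 and 2 adjusted over the list alone), including Hmcn2 (log2 fold change -5.63) and Calcr (-6.23). With camera's preset correlation this list fell (adjusted p = 5.58e-08), but adjusted p = 0.502 with an estimated correlation. Here and below, the estimated form rests on 3 residual degrees of freedom and has little power. The estimated correlation was 0.296 for this list and ran from -0.0104 to 0.945 over the injury lists, against the preset 0.01. In the antibody and ActD comparisons it ran from -0.012 to 0.752. Where genes of a list correlate more than the preset value, the preset p is too small. Without the 0 dpi aRW library 13 quiescence genes fell. Of the S phase genes 37 of 41 rose (38 adjusted over the list alone), such as the helicase gene Mcm2 (3.85), and of the G2 and M phase genes 50 of 53 (51 alone), such as the centromere histone gene Cenpa (7.27) and Birc5 (8.68). Their adjusted p was 3.52e-14 and 2.57e-22. It was 0.446 for each with an estimated correlation. A further 8 genes had 0 counts among 7904947 at 0 dpi. The fusion peptide gene Mymx was at least 624.5-fold higher at 4 dpi, the embryonic myosin Myh3 at least 324.9-fold, R3hdml at least 297.4-fold. Igfbp2 was at least 242.3-fold higher, the mitotic genes Pbk and Ccnb1 at least 149.6-fold and 139.6-fold, Prkg2 at least 127.9-fold and Hmmr at least 103.5-fold, all against a floor of 3 counts over the group. Of 33 genes of myogenic commitment and differentiation, 22 rose and 4 fell (22 and 5 alone; adjusted p = 5.99e-06, and adjusted p = 0.727 with an estimated correlation), and 1 fell without the 0 dpi aRW library.

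Other lists changed in part. Of 30 extracellular matrix genes 10 rose, among them tenascin C (Tnc, 7.24) and fibronectin (Fn1, 5.13), and 8 fell (10 and 8 adjusted over the list alone), and the list test did not pass (adjusted p = 0.201, and 0.822 with an estimated correlation). Of 49 oxidative phosphorylation genes 31 rose (36 alone; adjusted p = 7.96e-09, and adjusted p = 0.727 with an estimated correlation). In turn, 53 of 82 cytosolic ribosomal protein genes fell and 3 rose (54 and 3 alone; adjusted p = 9.39e-09, and adjusted p = 0.446 with an estimated correlation). Dissociation and immediate early genes fell for 16 of 41 and rose for 3 (17 and 3 alone; adjusted p = 0.00079, and adjusted p = 0.8004 with an estimated correlation). p53 targets rose for 10 of 19 and fell for 2 (11 and 2 alone; Zmat3 1.95), and interferon genes rose for 6 of 26 (4 alone; Bst2 2.83), each with an adjusted p of 0.0118, and adjusted p = 0.446 and 0.727 with an estimated correlation. Class I antigen presentation genes fell for 6 of 14 and rose for 1, heat shock genes rose for 2 and fell for 2 of 15, glycolysis genes rose for 2 and fell for 2 of 17, mitochondrially encoded genes rose for 2 and fell for 3 of 13, and the Notch-linked collagens rose for 2 of 5, with the same counts adjusted over each list alone. None of those list tests passed (adjusted p = 0.292, 0.842, 0.212, 0.4975 and 0.0722). Without the 0 dpi aRW library 18 oxidative phosphorylation and 3 interferon genes rose, and 10 immediate early and 3 extracellular matrix genes fell. Without aN2 at 4 dpi 11 oxidative phosphorylation genes and 6 p53 targets rose and 4 extracellular matrix genes fell. Extracellular matrix genes fell for 4 without the 0 dpi aN2 library and for 5 without either aRW library at 4 dpi. Without the 0 or 4 dpi library lacking antibody, 14 interferon, 9 glycolysis, 8 immediate early and 5 heat shock genes rose. Counts of 3 or fewer members also moved with most libraries. The heat shock median was -0.0047 while its test pointed up.

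Of 8 Notch target genes tested 4 fell and 1 rose (6 and 1 adjusted over the list alone). Hes1, a repressor induced by Notch, fell by 1.58 on the log2 scale (adjusted p = 0.00624), and Hey1, Heyl and Dtx4 had log2 fold changes of -1.82, -1.24 and -1.77, while the feedback regulator Nrarp had 2.06. These values average over conditions that include aN2. With ActD, the log2 change under aN2 minus that under aRW was -1.61 for Heyl, -1.26 for Dtx4 and -1.15 for Hey1. For Nrarp it was -1.75 and for Hes1 0.85. The list test did not pass (adjusted p = 0.0782, and adjusted p = 0.727 with an estimated correlation), nor did that of the Notch pathway list, with 7 of 28 up and 10 down (7 and 12 alone; adjusted p = 0.547, and 0.906 with an estimated correlation). Of that list 4 were up without the 0 dpi aRW library or aRW library 2 at 4 dpi, and 2, 5 and 6 were down without 0 dpi aRW, 0 dpi aN2 and 4 dpi aN2. Dll1 rose by 1.30 ± 0.37 (adjusted p = 0.0227). In Notch2-high cells alone, a fit chosen after seeing the data, Nrarp (1.09, adjusted p = 0.349) and Dll1 (0.67, adjusted p = 0.306) did not pass. The falls of Hes1, Hey1, Heyl and Dtx4 passed there. In the fit of Quiescence and Primary cells Dll1 turned to -0.18 (adjusted p = 0.768) and the calls of Heyl (-0.38, adjusted p = 0.258) and Dtx4 (-0.96, adjusted p = 0.0932) ended. Erythroid or differentiating markers led the Quiescence class in 2 of 3 libraries, so these are values only. Leaving out the 0 dpi aRW library ended the calls of Hes1 (adjusted p = 0.109), Hey1 (0.173), Heyl (0.0512), Dtx4 (0.213) and Nrarp (0.0936). Leaving out the 0 dpi aN2 library ended those of Hey1 (0.114), Heyl (0.142), Dtx4 (0.138) and Dll1 (0.0795). Leaving out aN2 at 4 dpi ended those of Hey1 (0.0705), Heyl (0.106), Dtx4 (0.0955) and Dll1 (0.102). Leaving out aRW library 1 at 4 dpi ended those of Hey1 (0.0551) and Dtx4 (0.0630). Without aRW library 2 the calls of Dtx4 (0.0541), Nrarp (0.0555) and Dll1 (0.0729) ended.

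Markers of other cells moved with time too. Macrophage or monocyte markers rose for 12 of 13 genes, and their summed level was 8.73 to 23.2 CPM at 0 dpi and 663, 111, 49.2 and 153 CPM in the matched 4 dpi libraries. Endothelial markers fell for 9 of 10 genes, erythroid markers for 4 of 4 and mature myofibre markers for 6 of 10, the last summing to 6571 to 13104 CPM at 0 dpi and 1688 to 4580 CPM in the matched 4 dpi libraries. Fibroblast markers fell for 5 of 11 and rose for 1, and pericyte or smooth muscle markers rose for 3 and fell for 4 of 8. Glial markers fell for 2 of 4, and lymphocyte markers for 1 of 3. Tenocyte markers rose for 1 of 6, with a median of -0.36, a mean of 0.26 and a test pointing up. Satellite markers fell for 9 of 10 and rose for 1, cycling markers rose for 15 of 17, and differentiating markers rose for 12 and fell for 3 of 20. No neutrophil marker had enough counts to be tested (0 to 1.93 CPM summed at 0 dpi). In all, 4308 genes were higher and 3831 lower at 4 dpi among 18855 tested in edgeR. The count of 8139 fell to 5046 without the 0 dpi aRW library, 5304 without the 0 dpi aN2 library and 4916 without the 4 dpi aN2 library. Cell numbers in the authors' files fell into 5 runs, of which 1 held both times with 1 aRW library each, too few for a test within it.

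The aN2 libraries at 4 dpi showed what changes when Notch2 is blocked during regeneration. Notch3, a receptor that is itself a Notch target, fell from 132.9 ± 14.995 CPM under aRW (n = 3) to 49.7 ± 1.71 under aN2 (n = 2), a log2 fold change of -1.59 ± 0.22 (edgeR adjusted p = 0.0273), and Dtx4, a Deltex family gene, from 40.7 ± 8.57 to 18.7 ± 7.01 CPM (-1.42 ± 0.18, adjusted p = 0.0273). Pax7, the transcription factor that marks satellite cells, fell from 37.4 ± 3.06 to 16.6 ± 4.96 CPM (-1.42 ± 0.24, adjusted p = 0.0306), and Myog rose from 791 ± 227 to 1995 ± 667 CPM (1.31 ± 0.19, adjusted p = 0.0273). The ligand gene Dll1 rose from 13.4 ± 3.49 to 45.4 ± 17.1 CPM (1.56 ± 0.26, adjusted p = 0.0305). Transcripts of the blocked receptor, Notch2, stood at 69.6 ± 15.5 and 52.5 ± 10.4 CPM and did not pass (adjusted p = 0.16), and Heyl at 115.8 ± 6.002 and 41.8 ± 3.60 CPM with a log2 fold change of -1.64 ± 0.38 (adjusted p = 0.0635). In GRCm38 coordinates, Notch2 lies on chromosome 3 at 98013527 to 98150361 (plus strand) and Dll1 on chromosome 17 at 15367354 to 15376872 (minus). Notch3 lies on chromosome 17 at 32120820 to 32166852 (minus) and Heyl on chromosome 4 at 123233556 to 123249875 (plus). Pax7 lies on chromosome 4 at 139737062 to 139833528 (minus) and Myog on chromosome 1 at 134289989 to 134292548 (plus), and all are protein-coding.

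Among 7 Notch target genes 2 fell and none rose (5 adjusted over the list alone), with a median of -1.16 (adjusted p = 6.74e-05, and adjusted p = 0.463 with an estimated correlation). The wider Notch pathway list had 2 of 27 up and 2 down (3 and 6 alone) with a median of -0.09, and its test did not pass (adjusted p = 0.1285, and 0.579 with an estimated correlation). Of 33 genes of myogenic commitment and differentiation 13 rose (26 alone), such as the fusogen gene Mymk (1.53 ± 0.18), Mef2a (1.23) and the troponin gene Tnnc1 (1.65), with an adjusted p of 4.86e-16, and adjusted p = 0.463 with an estimated correlation. The quiescence list had 3 of 27 genes down (13 alone), which were Pax7, Fgfr4 (-1.09) and Cdh15 (-0.86) (adjusted p = 5.08e-05, and adjusted p = 0.463 with an estimated correlation). Extracellular matrix genes fell for 9 of 30 (24 alone, with 1 up), including the basement membrane collagen Col4a2 (-2.79), the protease inhibitor Timp3 (-2.43), Mmp14 (-1.38) and the laminin Lama2 (-1.22), with an adjusted p of 4.91e-13, and adjusted p = 0.463 with an estimated correlation. Cytosolic ribosomal protein genes fell for 12 of 82 (44 alone, with 1 up), such as Rpl10 (-1.07; adjusted p = 1.12e-09, and adjusted p = 0.463 with an estimated correlation). Among S phase genes only E2f8 passed (1.18), and no member of the G2 and M phase, oxidative phosphorylation, interferon, immediate early, mitochondrially encoded or Notch-linked collagen lists did. These lists passed with the preset correlation (the largest adjusted p was 0.0285), and none did with an estimated one. The largest increases were in the pentraxin gene Nptx1 (7.30 ± 1.92 to 43.7 ± 0.846 CPM, adjusted p = 0.012), Qrfp (2.34), the transferrin receptor Tfrc (1.90), Tuba4a (1.78) and Trp53i11 (1.66). The largest decreases after Col4a2 and Timp3 were in Htra3 (-2.42), Capn6 (-2.38) and mt-Tw (-1.94). Each of these list counts was 0 without aRW library 1 with ActD, aRW without ActD or either aN2 library. Without aRW library 2, 23 myogenic and 13 S phase genes rose and 49 ribosomal protein, 18 extracellular matrix, 12 quiescence and 5 Notch pathway genes fell. With RLE scaling over all libraries 8 myogenic genes rose and 5 extracellular matrix and 3 ribosomal protein genes fell. DESeq2 gave 22, 18 and 35 of these. Without aDll1 library 1 or 2, 4 Notch target, 15 extracellular matrix and 5 quiescence genes fell. Beside these, differentiating markers rose for 5 of 20 genes, mature myofibre markers for 2 of 9 and tenocyte markers for 1 of 7. Satellite markers fell for 2 of 8, fibroblast markers for 1 of 10 and pericyte or smooth muscle markers for 1 of 6. Macrophage markers summed to 153 and 43.4 CPM under aN2 against 111, 49.2 and 803 CPM under aRW.

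Across 18295 genes 275 were higher and 392 lower under aN2. Leaving out aRW library 1 with ActD, aRW without ActD, or either aN2 library left 0 genes called by edgeR, with 3404, 1833, 2278 (without aN2 with ActD) and 1816 (without aN2 without ActD) at an unadjusted p under 0.05. Leaving out aRW library 2 gave 3651. The 4 aN2 and aRW libraries of a single run of cell numbers, a subset chosen after seeing the data, held 1 library per antibody and ActD setting. That fit has no replicate spread, so only effect sizes are read from it. Log2 fold changes were -1.71 for Notch3, -1.43 for Pax7 and 1.31 for Myog.

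**Figure D2:**
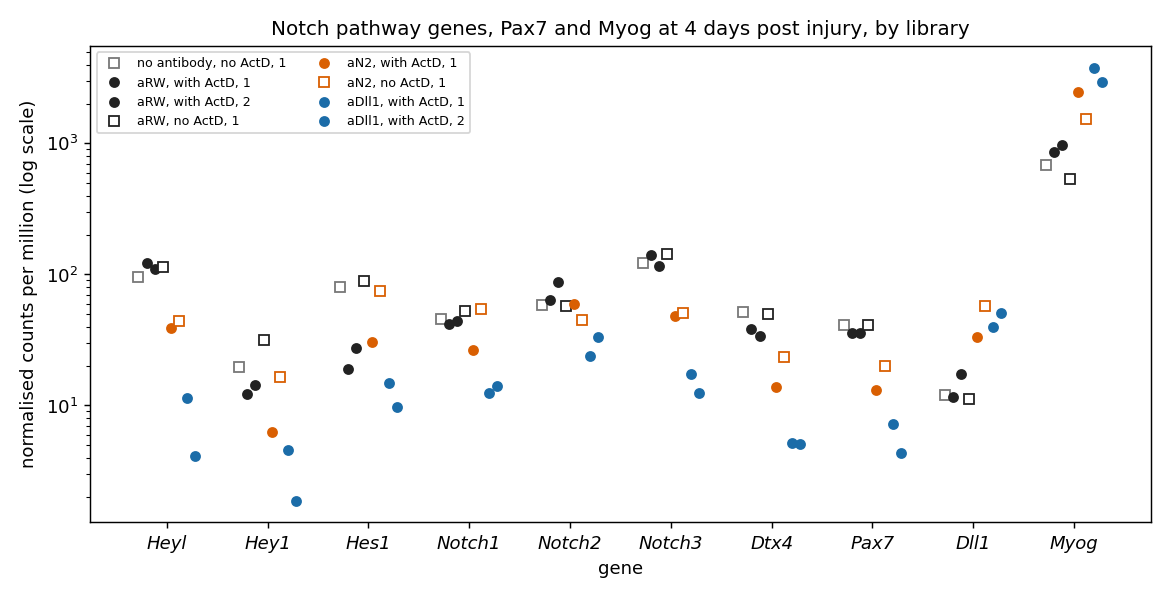
TMM-normalised CPM of Notch genes, Pax7 and Myog (logarithmic y axis) in each 4 dpi library, colored by antibody. Heyl stood at 110 to 122 CPM in the aRW libraries, 39.3 and 44.4 under aN2 and 11.4 and 4.13 under aDll1.

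Under aDll1, the antibody against the Notch ligand, the same model compared 2 libraries with the aRW libraries, all with ActD in the group means given here. Heyl, a repressor induced by Notch, fell from 116 ± 8.40 CPM (n = 2) to 7.78 ± 5.15 (n = 2), a log2 fold change of -3.93 ± 0.45 (edgeR adjusted p = 0.00421), and Notch3 from 128 ± 17.1 to 14.9 ± 3.41 CPM (-3.15 ± 0.25, adjusted p = 0.00161). Notch2 fell from 75.5 ± 16.5 to 28.5 ± 6.68 CPM (-1.42 ± 0.21, adjusted p = 0.00528) and Pax7 from 35.7 ± 0.116 to 5.77 ± 2.00 CPM (-2.61 ± 0.27, adjusted p = 0.00189). The Notch2 sum depends on the share of Notch2-high cells, which was lower under aDll1. Without a blocking antibody those cells held 250 ± 19.3 CPM of Notch2 and Primary cells 60.4 ± 5.34 (n = 4). Myog rose from 917 ± 84.8 to 3381 ± 583 CPM (1.88 ± 0.20, adjusted p = 0.00195), and Dll1 itself from 14.5 ± 4.10 to 45.3 ± 7.55 CPM (1.79 ± 0.26, adjusted p = 0.00528).

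Of 7 Notch target genes 6 fell (7 adjusted over the list alone), with a median of -2.80 (adjusted p = 1.52e-07, and adjusted p = 0.280 with an estimated correlation); Hes1, at -1.05, missed the threshold over all genes (adjusted p = 0.0558). The wider Notch pathway list had 9 of 27 down and 2 up (12 and 4 alone; adjusted p = 0.000983, and adjusted p = 0.280 with an estimated correlation). Of 33 myogenic genes 26 rose (26 alone), including Myod1, the myoblast determination factor (164 ± 20.1 to 616 ± 201 CPM), Mymk (1.82) and Tnnc1 (2.30), with an adjusted p of 8.94e-17, and adjusted p = 0.280 with an estimated correlation. The quiescence list had 15 of 27 down (19 alone, with 1 up), among them the growth factor receptors Egfr (-1.66) and Fgfr4 (-1.36) and the cadherin Cdh15 (-1.35; adjusted p = 1.52e-07, and adjusted p = 0.280 with an estimated correlation). Extracellular matrix genes fell for 22 of 30 (23 alone), including Timp3 (40.6 ± 14.5 to 1.58 ± 0.428 CPM), Tnc (107 ± 28.6 to 6.95 ± 2.82 CPM) and Mmp14 (-2.51), with an adjusted p of 1.54e-16, and adjusted p = 0.331 with an estimated correlation. The Notch-linked collagens fell for 3 of 5 (5 alone), with Col5a1 at -3.19 (adjusted p = 2.08e-05, and adjusted p = 0.370 with an estimated correlation). Without aRW library 1 with ActD, 10 myogenic genes rose and 7 quiescence genes and 1 collagen fell. Without aDll1 library 1, 13 myogenic genes rose, and without aDll1 library 2, 6 quiescence genes fell. In the aDll1 and aRW libraries with ActD alone 11 myogenic genes rose, and 15 extracellular matrix, 7 quiescence and 4 Notch target genes fell. Hey1 (adjusted p = 0.0612) and Nrarp (0.103) were not called there. The calls of Hey1 (adjusted p = 0.05998) and Nrarp (0.104) ended without aRW library 1, and that of Nrarp also without aRW library 2 (0.0652), aRW without ActD (0.0791), aN2 with ActD (0.0767) and aN2 without ActD (0.0816).

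Interferon genes fell for 8 of 27 (10 alone; adjusted p = 4.74e-05, and adjusted p = 0.653 with an estimated correlation) and immediate early genes for 13 of 41 with 1 up (16 and 2 alone; Klf6 -1.35; adjusted p = 0.0014, and adjusted p = 0.662 with an estimated correlation). Glycolysis genes rose for 5 of 17 (6 alone; Eno3 1.32; adjusted p = 4.74e-05, and adjusted p = 0.326 with an estimated correlation). Heat shock genes rose for 4 of 15 (7 alone, with 2 down; Hspb8 1.67; adjusted p = 0.00727, and adjusted p = 0.365 with an estimated correlation), and S phase genes for 5 of 41 (5 alone; E2f8 1.46; adjusted p = 0.00104, and adjusted p = 0.690 with an estimated correlation). Class I antigen presentation genes fell for 5 of 13 (6 alone; H2-T22 -1.36; adjusted p = 0.000631, and adjusted p = 0.601 with an estimated correlation). Without aRW library 1 with ActD, 1 gene each of the glycolysis, heat shock and S phase lists rose, and 0 interferon, 2 class I and 3 immediate early genes fell. Without aRW library 2, 11 S phase and 8 glycolysis genes rose and 17 interferon and 8 class I genes fell. Without aRW without ActD or either aN2 library, 1 S phase and 3 glycolysis genes rose, and without either aN2 library 5 interferon genes fell. Without aDll1 library 1, 1 S phase and 2 glycolysis genes rose and 1 interferon and 3 class I genes fell. Without aDll1 library 2, 2 S phase genes rose and 0 interferon, 2 class I and 3 immediate early genes fell. In the aDll1 and aRW libraries with ActD alone 1 S phase and 2 glycolysis genes rose, and 4 interferon, 4 class I and 2 immediate early genes fell. The largest increases included Nptx1 (2.58), the AMPK subunit gene Prkag3 (2.39), Tuba4a (2.11), Mybph (1.99), Ywhah (1.95) and Tfrc (1.89). The largest decreases were in Islr (-5.31), Wisp2 (-4.84), Col4a2 (-4.78) and the repressor gene Msc (-4.76). The call of Ywhah ended without aRW library 1 (adjusted p = 0.0519). Beside these, differentiating markers rose for 16 of 20 genes (4 without aRW library 1 and 6 without aDll1 library 1), mature myofibre markers for 5 of 9 (2 without aRW library 1 and 1 without aDll1 library 1, summing to 7873 and 4872 CPM against 2672 and 2433 CPM under aRW with ActD) and tenocyte markers for 1 of 7. Satellite markers fell for 4 of 8 and fibroblast and pericyte markers for 2 each of 10 and 6. No macrophage, endothelial, lymphocyte or glial marker passed (macrophage median 0.24, with a test pointing down; 306 CPM summed in aDll1 library 1 and 29.3 CPM in library 2).

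Class shares differed between the antibodies, so classes were also tested singly. Within Differentiation cells Heyl (-3.43, adjusted p = 0.0027), Notch3 (-2.94, adjusted p = 0.00105) and Pax7 (-2.85, adjusted p = 0.019) fell under aDll1. Dll1 (0.59, adjusted p = 0.161) and Notch2 (-1.11, adjusted p = 0.0924) did not pass. Under aN2 Heyl (-1.22, adjusted p = 0.121), Notch3 (-1.09, adjusted p = 0.087) and Dll1 (0.41, adjusted p = 0.338) did not pass in these cells. There 0 of the myogenic genes passed under either antibody (medians -0.02 under aDll1 and -0.07 under aN2). Within Primary cells edgeR called 0 genes for either antibody, with 2405 (aDll1) and 1702 (aN2) at an unadjusted p under 0.05. The aDll1 sums there came from 94 and 67 cells, against 670 and 870 under aRW with ActD. Notch target medians in Primary cells were -1.27 under aDll1 and -0.55 under aN2, so absence of an effect is not shown. Under aDll1 Notch2 had -1.20 in Primary cells (adjusted p = 0.214) and passed in Proliferation cells (-1.03, adjusted p = 0.0284). Also in Proliferation cells, Dll1 (1.345, edgeR adjusted p = 0.0165) and Myog (1.70, adjusted p = 0.00822) passed under aDll1. Under aN2 Heyl (-1.41, edgeR adjusted p = 0.0353) and Notch3 (-1.04, adjusted p = 0.0474) passed there, and Dll1 (1.03, adjusted p = 0.0896) did not. Proliferation did not meet the rule for comparing classes. Of 18295 genes 1018 were higher and 1628 lower under aDll1. Leaving out a library moved this count to 769 (aRW library 1 with ActD), 1496 (aRW without ActD), 1502 (aN2 with ActD), 1454 (aN2 without ActD), 1451 (aDll1 library 1) and 1155 (aDll1 library 2). Without aRW library 1 the call of Dll1 ended (adjusted p = 0.0513). Those of Islr and Wisp2 ended without each of the aRW and aN2 libraries (adjusted p = 0.0823 and 0.0837 without aRW library 1, 0.155 and 0.174 without aRW library 2, 0.182 and 0.167 without aRW without ActD, 0.195 and 0.175 without aN2 with ActD, and 0.184 and 0.167 without aN2 without ActD). Of the 68 genes called among those chosen by the naming rule, 35 stayed called whichever library was left out. Both aDll1 libraries formed a run of cell numbers that held 0 aRW libraries, so the antibody and the run cannot be told apart.

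Both antibody effects were then compared over the same 7 libraries. Fold changes under aN2 and aDll1 had a covariance of 0.387 across 18295 genes, against a mean of 0.072 and a highest value of 0.0819 in 50 simulated draws of unchanged groups sharing the same controls. Pearson's r was 0.578 (simulated 0.300) and Spearman's rho 0.555 (simulated 0.293). Genes are not independent replicates. The simulated groups also held no change in class shares, while Primary shares were lower and Differentiation shares higher under both antibodies. A common change in shares could therefore raise the covariance, and agreement within a class was not computed. Among called genes 256 were higher under both and 213 lower under both, where independent lists would share 15.3 and 34.9. Another 2 were in opposite directions. Simulated groups shared 0.3 and 0.02, but they held no antibody effect and so almost no called genes. Their overlap is therefore no baseline for these counts. The 3 controls could not be split with at least 2 libraries for each antibody, so part of the excess overlap of calls may come from shared controls. The simulated covariance already includes them. A direct test found 10 genes that differed between the antibodies, all with an edgeR adjusted p of 0.0461. Col18a1, a basement membrane collagen, had a log2 fold change of -1.04 under aN2 and -3.19 under aDll1. Ece1, an endothelin-converting enzyme, had -0.90 and -2.86, and the nuclear transport GTPase gene Ran -0.31 and 1.60. The other 7 were gene models or pseudogenes (Gm24276, Gm23493, Gm4760, Gm14747, Gm5451, Hspe1-ps3 and Rpl9-ps9), all lower under aN2 than under aDll1 and uncertain where reads are shared with their parent genes. The differences in Notch3 (1.55 ± 0.26, adjusted p = 0.0631), Dtx4 (1.38 ± 0.23, adjusted p = 0.0631), Heyl (2.29 ± 0.46, adjusted p = 0.111) and Pax7 (1.19 ± 0.29, adjusted p = 0.134) did not pass. Leaving out aRW library 1 with ActD, aRW without ActD, aN2 with ActD, aN2 without ActD or aDll1 library 2 left 0 genes in edgeR (2816, 1679, 1360, 1659 and 3491 at an unadjusted p under 0.05). Leaving out aRW library 2 gave 981, and DESeq2 on all libraries gave 641.

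**Figure D3:**
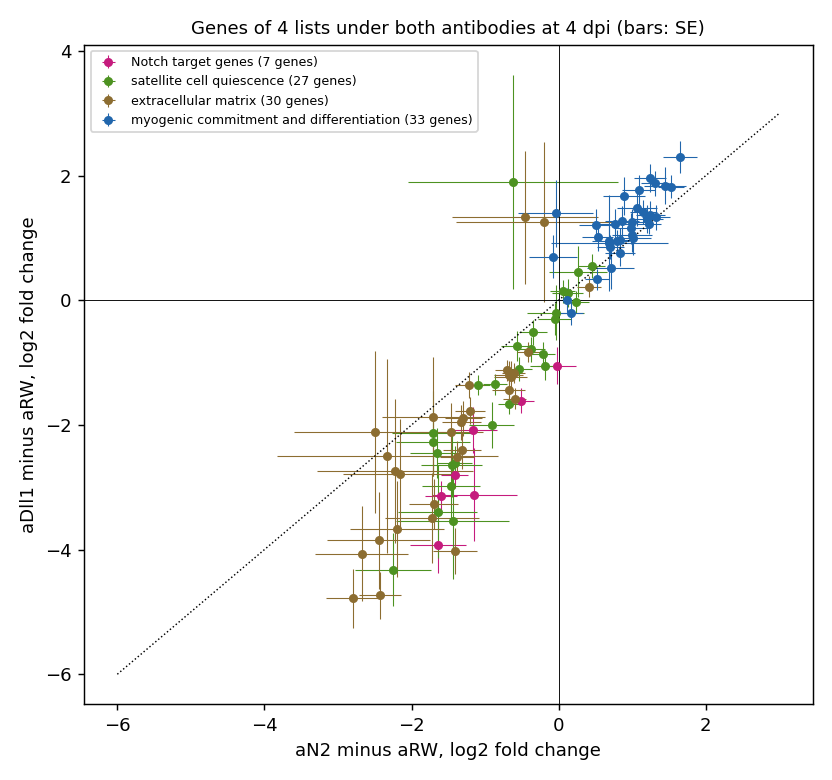
Log2 fold change against aRW under aN2 (x axis) and under aDll1 (y axis) at 4 dpi for 7 Notch target, 27 quiescence, 30 extracellular matrix and 33 myogenic genes, with SE bars. The dotted line marks equal fold changes.

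ActD was crossed with antibody for aRW and aN2, which gave its effect at 4 dpi. Immediate early genes, which respond within minutes to stress or dissociation, were lower with ActD. Trib1, a pseudokinase gene, stood at 119 ± 9.76 CPM without ActD (n = 2) and 1.53 ± 0.544 with it (n = 3), a log2 fold change of -6.30 ± 0.28 (edgeR adjusted p = 8.98e-05). Jun, an AP-1 subunit, fell from 302 ± 22.3 to 35.0 ± 1.74 CPM (-3.19 ± 0.16, adjusted p = 8.98e-05), and the Notch-induced repressor Hes1 from 82.2 ± 10.1 to 25.8 ± 6.07 CPM (-1.73 ± 0.26, adjusted p = 0.00374). Notch2 (0.33 ± 0.19, adjusted p = 0.246) and Heyl (-0.12 ± 0.36, adjusted p = 0.832) did not pass.

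Of 41 dissociation and immediate early genes 40 fell (40 adjusted over the list alone), including Csrnp1 (-5.31), Klf4 (-4.75), Ier5 (-4.53), Sgk1 (-4.52) and Dusp1 (-4.34), with an adjusted p of 3.63e-29, and adjusted p = 0.398 with an estimated correlation. p53 targets fell for 7 of 19 (10 alone, with 2 up), such as Bbc3 (-3.14), Plk2 (-3.25) and Mdm2 (-1.83; adjusted p = 0.00369, and adjusted p = 0.398 with an estimated correlation). Heat shock genes fell for 5 and rose for 2 of 15 (5 and 3 alone; Hspa1a -3.68; adjusted p = 0.206). In the other direction 44 of 82 cytosolic ribosomal protein genes rose (55 alone; Rps26 1.69, Rpl39 1.61; adjusted p = 5.79e-17, and adjusted p = 0.398 with an estimated correlation). So did 23 of 49 oxidative phosphorylation genes (28 alone; Atp5h 1.36; adjusted p = 5.15e-09, and adjusted p = 0.760 with an estimated correlation). Notch target genes fell for 4 of 7 (4 alone; adjusted p = 0.0249, and adjusted p = 0.760 with an estimated correlation). The gene mt-Nd2 (-1.66) was 1 of 2 mitochondrially encoded genes of 13 that fell. Glycolysis genes rose for 3 and fell for 3 of 17 (4 and 3 alone), among them hexokinase 2 (Hk2, -3.02), with a median of 0.10, a mean of -0.03 and a test pointing up (adjusted p = 0.724). The mitochondrial tRNA gene mt-Ts2 (3.38), the small nuclear RNA Rn7sk (3.19) and mt-Tl2 (3.14) led the increases. Pseudogenes such as Anp32b-ps1 (2.97) followed and are uncertain. Beside these, 4 of 20 differentiating markers rose, and macrophage markers, none of 13 past the threshold, had a median of -1.42.

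With ActD 1895 genes were higher and 2599 lower among 18295. Leaving out aRW without ActD reduced the count to 408 and ended the calls of the Notch targets Hes1 (adjusted p = 0.114), Hey1 (0.189), Dtx4 (0.255) and Notch1 (0.112). Without aN2 with ActD those of Hey1 (0.0837), Dtx4 (0.244) and Notch1 (0.4096) ended, and without aN2 without ActD the same 3 (0.0938, 0.254 and 0.4201). Without aRW library 1 with ActD those of Hey1 (0.0622) and Notch1 (0.0559) ended. The calls of mt-Ts2 and mt-Tl2 ended without aRW without ActD (0.351 and 0.387), aN2 with ActD (0.222 and 0.231), aN2 without ActD (0.223 and 0.234), aDll1 library 1 (0.0626 and 0.0724) and aDll1 library 2 (0.0628 and 0.0724). Without aRW without ActD, 26 immediate early genes and 4 p53 targets fell, and 7 ribosomal protein and 0 oxidative phosphorylation genes rose. Without aN2 with ActD 11 ribosomal protein and 2 oxidative phosphorylation genes rose, and without aN2 without ActD 9 and 1. In counts, leaving out aN2 with or without ActD gave 1259 and 1062 genes. Within the 4 libraries of a single run of cell numbers, chosen after seeing the data, the median log2 fold change of the immediate early genes was -2.76. That fit held 1 library per antibody and ActD setting and has no replicate spread, so only this effect size is read from it.

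Notch genes were also compared between the Differentiation and Primary classes within each of 4 libraries at 4 dpi without a blocking antibody. The ligand Dll1 was higher in Differentiation cells, at 43.8 ± 11.2 CPM against 5.37 ± 1.30 in Primary cells (n = 4; log2 fold change 3.10 ± 0.18, edgeR adjusted p = 4.88e-12). So was Hes6, a Hes family member linked to myogenic differentiation, at 468 ± 66.7 against 112 ± 26.8 CPM. Heyl was lower in Differentiation cells, at 44.7 ± 2.42 against 194 ± 26.1 CPM (-1.997 ± 0.0893, adjusted p = 4.38e-15), and Notch3 at 48.7 ± 0.964 against 215 ± 38.7 CPM (-2.01 ± 0.10, adjusted p = 1.37e-14). Of 26 Notch pathway genes tested 6 were higher (also Mfng, Jag2, Rbpj and Numbl) and 9 lower, including Nrarp (-2.18), the ligand Jag1 (-2.06), Dtx4 (-1.72), Hey1 (-1.59), Notch1 (-0.75) and Notch2 (-0.60). The call of Jag2 ended without aRW without ActD (adjusted p = 0.223) and that of Numbl without aRW library 2 (adjusted p = 0.111). The genes used to make the classes are unknown here, so this contrast is not independent of them and other genes are not reported.

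At 0 dpi, aN2 and aRW, each with ActD, were represented by 1 library each, so values carry 95% counting intervals, which cover counting error only, and no test. Notch2 stood at 191 CPM (175 to 209) under aRW and 236 CPM (220 to 254, as counted without TMM) under aN2, a ratio of 1.24 (1.10 to 1.39). Heyl was at 189 and 187 CPM (ratio 0.988, 0.876 to 1.11), Notch3 at 237 and 268 CPM (1.13, 1.02 to 1.25), Dll1 at 8.73 and 13.1 CPM (1.502, 0.883 to 2.617) and Hes1 at 116 and 81.8 CPM (0.707, 0.597 to 0.836). The median log2 ratio of 6 measured Notch target genes was 0.0018 (counting range -0.142 to 0.140), at percentile 26.8 of 10000 random lists of matched expression. In cells with at least 1000 genes it was -0.283 (-0.381 to -0.0509), at percentile 0.64. Over all cells the median of 29 quiescence genes was 0.161 (percentile 97.4). It was 0.171 (97.75) in cells with at least 500 genes, 0.0765 (77.6) with at least 1000, and 0.047 (44.1) in Quiescence cells. Over all cells immediate early genes were lower for 30 of 38 members (median -0.414, percentile 0.0), as were 19 of 27 myogenic genes (-0.389, 0.0) and 34 of 49 oxidative phosphorylation genes (-0.0829, 0.02). The largest ratios were in C1qtnf3 (25.8 to 94.0 CPM, 3.64), Myod1 (34.2 to 111 CPM, 3.26), Esr1 (3.05) and mt-Tg (2.79). The smallest were in the slow muscle genes Myl3 (0.0959), Myl2 (0.121) and Tnnc1 (0.157) and in Fabp3 (0.241) and Dhrs3 (0.257). Mature myofibre markers summed to 12473 CPM under aRW and 6571 CPM under aN2. Myog, with 29 and 130 UMIs, came from 5 of 1679 and 16 of 1447 cells.

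Whether the aN2 effect differed between 0 and 4 dpi was tested over 5 libraries with 1 residual degree of freedom. The effect at 4 dpi minus that at 0 dpi was -1.61 ± 0.52 for Heyl, -1.64 ± 0.55 for Notch3, -1.77 ± 0.49 for Pax7 and -1.26 ± 0.48 for Dtx4 on the log2 scale (SE), each with an edgeR adjusted p of 0.951. edgeR called 0 of 18911 genes, with 952 at an unadjusted p under 0.05, and DESeq2 called 2. In simulated data for this design edgeR recovered 2% of genes changed by 1 on the log2 scale and 20% of those changed by 2.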

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

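The tests of the fall of Notch target genes (on class fits that were planned and a single-run fit that was not), the depth and barcode base composition of the Notch2-high class and the regroupings of libraries and classes were chosen after the result was seen; the tests on shared barcodes, the barcode model and the fibre transcripts were set before their values were computed.

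Notch target genes fell under both antibodies while class shares changed, so a shift in shares might explain the fall. Within Differentiation cells their median log2 fold change was -2.13 under aDll1, with 3 of 7 past the threshold. This argues against shares of the annotated classes as the whole cause there. Under aN2 the median was -0.9096 with 0 past the threshold, which leaves shares open. A shift of cells within the class and free RNA from other cells were not tested. Under aDll1, extracellular matrix genes also fell there for 17 of 27 (median -1.83), while 0 of 33 myogenic genes passed (median -0.02). Differentiation cells took the place of Proliferation cells, which do not meet the rule for comparing classes, after both had been seen, and this turned the reading for aN2 from against shares to open (Proliferation -0.898, 2 of 7 past the threshold). Notch2-high cells (-1.27 under aN2, 3 of 6) carried no marker of any class among their leading genes, so a shift of cell types among them is not excluded. Among the 4 libraries of a single run the aN2 median was -1.15, so the fall also appeared where the run did not differ. That fit has no replicate libraries, so differences between single libraries remain open. For aDll1 0 runs also held aRW, so a run effect remains open.

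The Notch2-high class appeared in all 11 libraries, and its cell barcodes were richer in A and T than those of other cells by a mean of 5.999 percentage points (3.15 to 10.1, higher in 11 of 11; permutation p = 0.0001, the smallest possible), which points to a technical part in the class. A barcode model trained on the other libraries separated the class with an AUC of at least 0.606. Pairs of cells with the same barcode in different libraries were Notch2-high in both for 9 of 322 (permutation mean 6.79, highest 18, p = 0.239). The bound set in advance, a p of at least 0.05, would have excluded particular barcodes, but with so few pairs it could not, so this stays open. The class had the lowest median UMI count in 10 of 11 libraries, so depth could contribute and remains open.

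Mature myofibre transcripts summed to 13104, 12473 and 6571 CPM at 0 dpi. Free RNA from fibres may contribute, and the ratio of their share in the shallowest cells to that in the deepest was 0.868 without antibody, 1.11 with aRW and 1.13 with aN2. For satellite markers it was 1.29, 1.33 and 1.397, so a ratio above 1 is not particular to fibre transcripts, and free RNA stays open. The top 5% of cells held between 14.3% and 16.4% of these transcripts in the 3 libraries, which argues against a few cells carrying fibre fragments.

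The 10 genes that differed between the antibodies stood out as a difference between groups, which was tested directly. The tdTomato reporter, which entered library sizes and fits but was not examined above, had a median of 1668 CPM over the libraries, from 684.5 and 835.7 under aDll1 to 2577 with aRW at 0 dpi. Of 34 regroupings of the injury libraries 1, the real one, gave as many genes as the 8139 found, and the highest other gave 0. These regroupings mixed conditions, and every other one left the time effect in the residual spread, so few calls could arise. Within conditions there are 12 regroupings, with a smallest possible exact permutation p of 0.0833, so chance is not excluded. Of 8 regroupings of the classes 1 gave as many as the real one, and the highest other gave 0, too few regroupings to exclude chance.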

How the results depend on the processing

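The cause was not tested for any of these changes unless stated. Fewer libraries or cells lower power by construction. Values in Proliferation cells rest on a class that Lyz2 led in aRW library 2 with ActD, and those in Quiescence cells on a class led by erythroid markers at 0 dpi without antibody and by differentiating markers with aN2. No call shared with an alternative changed direction. The fits on a single run held 1 library per antibody and ActD setting and have no replicate spread. Their counts of called genes below are listed for completeness only. They cannot be compared with the other counts and show nothing about how far the results depend on the processing. For injury (8139 genes) Notch2-high cells alone gave 5136, and other alternatives ran from 5752 to 9921. For aN2 (667) DESeq2 gave 2172, RLE scaling 355, no filter 2752, Primary cells 0 (1702 at an unadjusted p under 0.05 in edgeR), Proliferation cells 38, Differentiation cells 37 and the libraries of a single run 6756. For aDll1 (2646) Primary cells gave 0 (2405 at an unadjusted p under 0.05), Proliferation cells 727, Differentiation cells 281, and the aDll1 and aRW libraries with ActD alone 901. A replicate block on library numbers in those 4 libraries gave 3297. The difference of library 2 from library 1 correlated between the antibodies with r of 0.301 over all genes and 0.374 over the more abundant, and the number is only a label. Under the block Islr, Wisp2, Nrarp, Atp5g3, Cycs and Ccnb1 were no longer called and Aurka, Fas, Rps12 and mt-Nd3 were newly called. For ActD (4494) Primary cells gave 2101 and a single run 8493. For aN2 minus aDll1 (10) DESeq2 gave 641, RLE 1, no filter 1248, Primary cells 0 (1469 at an unadjusted p under 0.05), Proliferation cells 41, Differentiation cells 28, all but ECM cells 26 and thinned counts 28. For antibody by time (0) DESeq2 gave 2, RLE 1, no filter 18, Notch2-high cells 23 and thinned counts 34. With an estimated correlation 0 lists passed in each of 4 comparisons, where the preset called 9, 14, 15 and 9. The covariance of antibody effects was 0.243 at an average log2 CPM of at least 6. At 0 dpi the Notch target median reversed to -0.28 in cells with at least 1000 genes, the quiescence median was 0.047 in Quiescence cells, and the log2 ratio of Sdc4 reversed to 0.040. Pgam2 reversed to -0.11 under aDll1 in Differentiation cells and Dll1 to -0.18 at 4 dpi in Quiescence and Primary cells. Leaving out single libraries gave 4916 to 8966 genes for injury, 0 to 3651 for aN2, 769 to 3278 for aDll1, 408 to 6014 for ActD, 0 to 981 for aN2 minus aDll1, 5385 to 5667 between classes, and a Differentiation difference under aDll1 of 21.4 to 32.3 points. Depth limits the 0 dpi results, where the fewest UMIs were counted.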

Other observations

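No tests were run on these values, which were chosen after the result was seen. The ubiquitin-conjugating enzyme gene Ube2c stood at 1086 CPM in the 0 dpi library without antibody and at 93.6 and 49.5 CPM in the other 0 dpi libraries. Erythroid markers summed to 210.3, 62.3 and 115.5 CPM at 0 dpi (no antibody, aRW, aN2) and to at most 6.51 CPM at 4 dpi. Neutrophil markers summed to 2.26 to 23.2 CPM at 4 dpi.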
